A study of Homo sapiens with 4 samples.

How the data were processed

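CUT&Tag of CHAF1A in RBE cells was analysed from 2 peak lists, 1 for the control siRNA group and 1 for the CHAF1A siRNA group, each group having 2 samples. The labels do not say whether the samples of a group were pooled, merged or represented by 1 of them, and whether a control library served as background is not given in the sources used here. The lists were assigned to the groups from their names (NC and si), which match the sample titles only in part. Per the submitters' processing notes, the tools were fastp 0.20.1, Bowtie2 2.2.5, MACS2 2.1.2 and deepTools 3.4.3, with the build hg38. In the deposited lists, fold enrichment is a linear ratio of the pileup at the summit to its background. The p and q of each peak are deposited as −log10 values, and the deposited score is a whole number that follows −log10 q and was not used. Peak starts, ends and summit offsets are as deposited, printed here counting from 1. The lowest −log10 p in each list was 5.00, so the authors called peaks at a p of 1e-05.

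Peaks on chromosomes 1 to 22, X and Y were kept, which left out 868 control and 886 siRNA peaks on other sequences; no rows shared an interval. MACS2 computes the fold as (pileup + 1)/(background + 1) and p as the Poisson tail of the pileup, so both were solved for pileup and background at each summit with −log10 p under 290. Of the peaks, 99.1% in each list could be solved, and over 99.9% of those gave a whole pileup within 0.02 reads. The most frequent background, taken as that of the whole genome, was 6.34 reads for the control and 8.49 for the siRNA list. It is proportional to reads times fragment length of the data that set it, and the number of reads itself was not used here. To test depth, siRNA pileups and backgrounds were thinned at random to the control background (1 fixed seed) and peaks still past the threshold were kept. On simulated data, all of 17731 pileups were recovered, thinning gave 1.00 times the peaks of fresh shallower draws, and overlaps of 2000 intervals were the same as those of bedtools. The simulated sites for thinning shared 1 mean and 1 background and were not first selected for passing the threshold. That check therefore does not cover weak peaks near the threshold.

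Gene positions came from an NCBI RefSeq gene table of GRCh38.p14, matched to the lists by chromosome and position. The plan, written before the data were examined, asked for windows around 5′ ends, a share of repeats under the peaks and random lists matched on GC content. Genome sequence, strand, transcripts and repeats were not used here. Windows of 1 kb around either gene end took the place of 5′ ends, random lists were matched on 10 classes of gene length, and the share of repeats, and so of transposable elements, was not analysed here. Some windows therefore lie at 3′ ends. Random placement (100 repeats) kept chromosome and width and used 100-kb bins that held a gene or a peak. Random shifts were of up to 500 kb.

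Sharing meant overlap by at least 1 bp. The 22 gene lists (21 written out and 1 defined by symbol and chromosome) and the rule for named genes were fixed before the data were examined. The rule took CHAF1A and NAT10, the 8 genes with the highest −log10 q in both lists, the control list only and the siRNA list only, 3 regions per class outside gene ends, and up to 4 genes per list by control strength and 4 with a peak in 1 list only. Some genes that the rule takes are not reported here. CHD7, ARID1B, PROM1, G6PC1, ZNF875 and the tRNA genes were named outside it, after their values had been seen. Each list's percentile was taken among 10000 random lists of protein-coding genes, and neighbouring genes can share a peak. The percentile of the difference between the lists used random genes that also had as many control peaks; it was added after the data had been seen, as were the comparisons of gene classes, tRNA genes and chromosomes and the genes whose peaks are not shared past the window. Alternatives were −log10 q of at least 5 and of at least 10, equal numbers of peaks per list, 50% reciprocal overlap, a 3 kb window, every sequence in the lists, every row counted, unmatched random lists, and, added later, thinning, random shifts, a 200 bp margin around tRNA genes and leaving out chromosome 6.

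There is 1 list per group, so no test between conditions was made. Intervals of shares are 95% exact binomial intervals, and those of medians come from 1000 bootstrap draws of summits; all cover counting error only. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.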

Results

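CHAF1A, the large subunit of the histone chaperone CAF-1, was mapped on chromatin by CUT&Tag in RBE cells, an established human line of intrahepatic cholangiocarcinoma. CAF-1 places new histones on DNA behind the replication fork. In CUT&Tag an antibody brings a transposase to the sites of its target, so that the sequenced fragments pile up where the target sits. The cells received a control siRNA (2 samples) or an siRNA against CHAF1A (2 samples) and were collected 48 hours after transfection. The title of the series links CHAF1A to NAT10, the enzyme that makes N4-acetylcytidine in RNA, and to the silencing of transposable elements. 2 peak lists were analysed, 1 per group. The list named NC is read here as the control siRNA list and the list named si as the CHAF1A siRNA list. Neither list keeps the 2 samples of its group apart, so no difference below has a replicate check and no p-value between conditions is given. The 95% exact binomial (Clopper-Pearson) intervals cover counting error only. Fold enrichment and −log10 q are the authors' values for each peak within its own list. They depend on the depth of that list, so a difference in them between the lists is not read as a change in binding.

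On chromosomes 1 to 22, X and Y the control list held 76313 peaks that covered 32.1 Mb, and the siRNA list held 97653 peaks that covered 43.1 Mb. The median peak was 327 bp wide with a fold enrichment of 3.72 in the control list, and 340 bp wide with a fold enrichment of 3.19 in the siRNA list. Read totals were not used here. The background recovered from the peak values was 6.34 overlapping reads per position for the control list and 8.49 for the siRNA list. If the CUT&Tag data themselves set this background, those behind the siRNA list were 1.34 times as deep, in reads times fragment length. Weaker sites could then pass its threshold.

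The first comparison asks which peaks of CHAF1A CUT&Tag are found with and without the knockdown. No untargeted control library was used here, so a peak is a site of signal, and CHAF1A occupancy was not separated from access of the transposase to open chromatin. The strongest sites at gene ends were present in both lists. They lay at RBM39, a splicing factor gene, at the gene pair FGFR1OP2 and INTS13, which share 1 peak, and at MED1, RC3H2, UPF3A and NKTR. The RBM39 peak (GRCh38, chromosome 20, 35741700 to 35742689) had a −log10 q of 3616 in the control list, and a siRNA peak covered the same site at 35741682 to 35742719. MED1 encodes a subunit of the Mediator complex and UPF3A a factor of nonsense-mediated mRNA decay. Their control peaks had −log10 q of 1782 and 1656.

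The 2 genes that the study is about carried a peak in each list. At CHAF1A itself (chromosome 19, 4402640 to 4450830) the control peak spanned 4402301 to 4402844 with a fold enrichment of 13.96, and the siRNA peak spanned 4402306 to 4402948 with a fold enrichment of 12.5. At NAT10 (chromosome 11, 34105629 to 34146908) the control peak spanned 34105058 to 34105708 with a fold enrichment of 6.74. The siRNA peak at NAT10 spanned 34104840 to 34105798 with a fold enrichment of 4.77. An siRNA acts on RNA, so a peak on the CHAF1A gene does not check the knockdown, and RNA or protein levels of CHAF1A were not analysed here.

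Of the control peaks, 47221 (61.9%, 61.5 to 62.2) were overlapped by at least 1 bp of a siRNA peak. Of the siRNA peaks, 46416 (47.5%, 47.2 to 47.8) were overlapped by a control peak. Random placement of the other list gave 3.36% and 2.64%, and shifts of up to 500 kb gave 5.93% and 4.68%. Sharing followed strength within each list. Among the 10% of control peaks with the lowest −log10 q, 29.5% were shared, against 97.8% of the 10% with the highest. In the siRNA list these shares were 13.7% and 98.9%. With −log10 q of at least 10, the control list kept 37115 peaks and the siRNA list 38805.

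**Figure D1:**
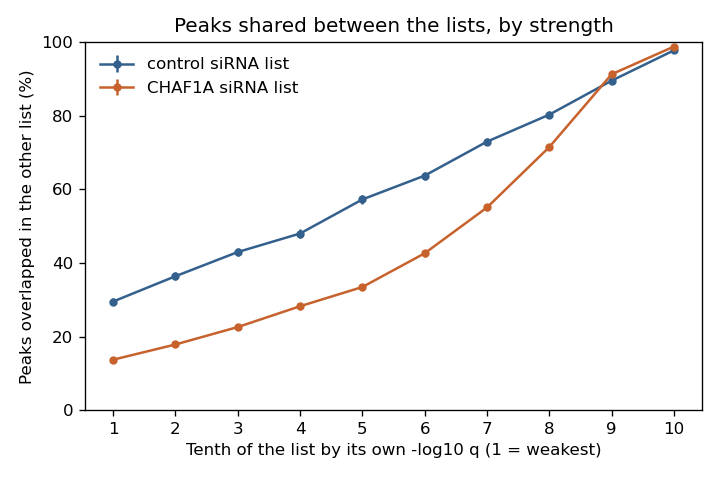
Share of peaks (percent, vertical axis) overlapped by at least 1 bp of a peak of the other list, by 10 equal groups of each list's own −log10 q (horizontal axis, weakest at 1); points are shares and bars 95% exact intervals. The share goes from 29.5% to 97.8% in the control list and from 13.7% to 98.9% in the siRNA list.

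Some strong sites away from gene ends were also shared. The peak on chromosome 3 at 93470362 to 93470829 had a fold enrichment of 36.6 in the control list, and the peak on chromosome 17 at 22521207 to 22521751 had 61.9. A further shared peak on chromosome 13 (109424132 to 109424332) had 43.7. Among sites of the control list only, the highest −log10 q (3478) was on chromosome 1 at 629128 to 629417, over MTND1P23, a nuclear copy of mitochondrial DNA. The next control-only sites were on chromosome 17 (21960369 to 21960555) and chromosome 19 (835409 to 835581), outside annotated genes. Among sites of the siRNA list only, the strongest lay on chromosome 5 at 123761052 to 123761328, with a fold enrichment of 53.7. The next lay in PCBD2 over the mitochondrial pseudogene MTND4P12 (chromosome 5, 134927038 to 134927389) and in the T cell receptor beta locus (chromosome 7, 142666121 to 142666824). No filter for regions prone to alignment pile-ups was applied here. The chromosome 1 site had its −log10 q of 3478 at a fold enrichment of only 2.92. Pile-ups of that kind were thus not separated from CHAF1A signal at any site of this paragraph, shared or not.

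The second comparison asks which genes have a peak at their ends. Since strand was not used here, a gene end is either boundary of an annotated gene, with 1 kb on each side. Peaks were concentrated there: 13361 control peaks (17.5%, 17.2 to 17.8) and 14776 siRNA peaks (15.1%, 14.9 to 15.4) lay at an end of a protein-coding gene, against 3.53% and 3.58% of randomly placed peaks. The concentration was stronger in the shared peaks, of which 23.7% in each list lay at gene ends. Peaks of the control list only had 7.53% at gene ends and peaks of the siRNA list only 7.41%, also above random placement. Location followed strength as sharing did. Between the 10% of peaks with the lowest and the highest −log10 q, the share at gene ends rose from 7.56% to 43.7% in the control list. In the siRNA list it rose from 6.19% to 45.2%. Being shared and being strong were therefore not separated in this comparison. Elsewhere in protein-coding genes lay 40.3% of control and 42.3% of siRNA peaks, and outside annotated genes 30.7% and 31.2%.

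Of 20037 protein-coding genes, 11258 had a peak at an end in both lists, 982 in the control list only, 1616 in the siRNA list only and 6181 in neither. With equal numbers of peaks per list, 1227 genes had a control peak only and 1252 a siRNA peak only, so the excess of siRNA-only genes was not separable from the length of the lists. In the lists as deposited, 92.0% of the 12240 control genes also had a peak in the siRNA list. The peaks of a gene in both lists need not overlap or lie at the same end. The control-only genes with the highest −log10 q were the neighbours MRPL28 and PGAP6, which share a peak (chromosome 16, 370271 to 370666, fold enrichment 6.02), and NEBL, KIR2DL1, H3-3B, MXD4, B4GALT4 and ITGA7. H3-3B encodes the replication-independent histone H3.3. Its control peak lay at chromosome 17, 75779767 to 75780109, with a fold enrichment of 5.28 and a −log10 q of 63.2. MXD4 encodes a repressor of the MYC network and had a fold enrichment of 5.12.

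The siRNA-only genes with the highest −log10 q were CPNE9, KLHL12, SELENON, LAD1, LOC128092249, LCA5, KIF11 and ACBD4. In 7 of these 8 the siRNA peak overlapped a control peak that lay outside the 1 kb window, so only KIF11, a mitotic kinesin gene, had a site absent from the control list. The KIF11 peak spanned 92592900 to 92593345 on chromosome 10 with a fold enrichment of 6.09 and a −log10 q of 46.7. Among the control-only genes named, the peak of KIR2DL1 was shared in this way. Leaving out all genes with such peaks left 945 control-only and 1523 siRNA-only genes. Among the latter, chosen after the values were seen, KIF11 was followed by CREBBP (fold enrichment 5.41), a histone acetyltransferase gene, and by C12orf71, DRC2, ZNF629, USP28, INTU and DND1.

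The third comparison sets 22 gene lists side by side, each against 10000 random lists of the same size and matched gene length, as a description of these peak lists. Genes of chromatin, replication, RNA and cell division had peaks more often than random genes, and markers of other cell types less often, in both lists. Above the 97.5th percentile in both lists were histone chaperones, replication fork proteins, core histones, silencing factors of transposable elements, RNA modification enzymes, chromatin remodellers, drivers of cholangiocarcinoma, ribosomal proteins, mitotic genes, DNA damage response genes and chromosome 19 zinc finger genes. The list called DNA damage response genes here also holds p53 targets. Immediate early genes were at percentiles of 99.5 in the control and 91.1 in the siRNA list, and the difference of 2 genes was itself ordinary (percentile 24.6 among random lists with as many control peaks). Markers of hepatocytes, fibroblasts, endothelium, immune cells, neurons and the germline stayed at or under a percentile of 2.28 in both lists. Some of these positions were lost under other settings. Without matching on gene length, core histones stood at percentiles of 46.7 and 56.9. With the 3 kb window, zinc finger genes stood at 49.5 and 93.9, cholangiocarcinoma drivers at 93.5 in the control list, replication fork genes at 82.5 in the siRNA list and endothelial markers at 7.45 in the control list.

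**Figure D2:**
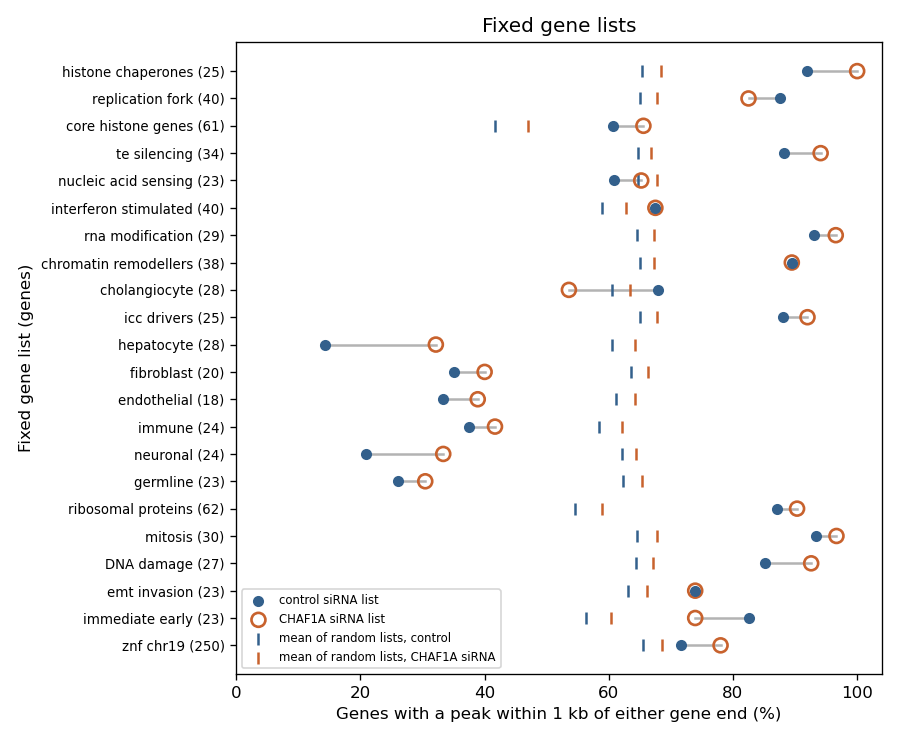
Genes of each list (vertical axis, number of genes in brackets) with a peak within 1 kb of either gene end, in percent (horizontal axis); filled points are the control list, open points the siRNA list and ticks the means of 10000 random lists. Histone chaperone genes reach 92.0% in the control list and all 25 genes in the siRNA list, while hepatocyte markers are at 14.3% and 32.1%.

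All 25 histone chaperone genes had a peak in the siRNA list and 23 in the control list, which lacked ATRX and SET. NPM1 (fold enrichment 15.1), MMS22L (20.1), CHAF1A and ASF1B had the strongest control peaks. Of 40 replication fork genes, 35 had a control and 33 a siRNA peak. RFC5 and GINS4 led the control list with fold enrichments of 13.7 and 11.9, and MCM5, CDT1 and POLD3 were in the control list only and CDC7 in the siRNA list only. The MCM5 peak, at a subunit of the replicative helicase, had a −log10 q of 19.7. Core histone genes had 37 control and 40 siRNA peaks among 61, with H4C2, H2BC3 and H2BC6 in the siRNA list only. That order turned with equal numbers of peaks per list, at 37 and 35.

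Among 34 silencing factors of transposable elements, 30 had a control and 32 a siRNA peak. HELLS, a chromatin remodeller needed for DNA methylation, had a fold enrichment of 15.3 in the control list and CBX5, the heterochromatin protein HP1 alpha, 8.23. DNMT3B and EHMT2, a DNA and a histone methyltransferase gene, had a peak in the siRNA list only, with −log10 q of 7.13 and 6.68. Genes that sense nucleic acids were not set apart from random lists, with 14 control and 15 siRNA genes of 23 (percentiles 34.9 and 39.2). RIGI, the receptor of short double-stranded RNA, had a control peak only (fold enrichment 7.49), and ADAR and TLR9 a siRNA peak only. Interferon-stimulated genes had 27 of 40 in each list (percentiles 86.8 and 73.1). STAT2 and IRF1 had the strongest control peaks, USP18 and OAS2 were in the control list only, and OAS3 and HLA-B in the siRNA list only.

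RNA modification enzymes had 27 control and 28 siRNA genes of 29, led by RBM15 (fold enrichment 13.8) and METTL16 (15.7), with NSUN5 in the siRNA list only. Chromatin remodellers had 34 of 38 in each list. SMARCA5, the ISWI ATPase, had a control fold enrichment of 21.8, and 3 genes differed each way: BAZ1A, MBD3 and CHD7 were in the control list only and MTA1, ARID1B and BRD9 in the siRNA list only, BRD9 with a peak shared outside the window. Driver genes of cholangiocarcinoma had 22 and 23 of 25, with ERBB3 and BAP1 among the strongest control peaks and EPHA2 in the siRNA list only. The ERBB3 peak (56104003 to 56105022) lay outside the gene, past its boundary at 56103505, and may belong to a neighbouring gene. Ribosomal protein genes had 54 and 56 of 62 and mitotic genes 28 and 29 of 30, led by CDC20. The list of p53 targets and DNA damage response genes had 23 and 25 of 27, led by XPC and RRM2B. CDKN1A, BBC3 and ZMAT3 had a siRNA peak only and AEN a control peak only. Genes of invasion had 17 of 23 in each list, with ITGB1, TGFBR2 and VIM leading. Immediate early genes had 19 and 17 of 23, and KLF2 and NR4A1 were in the control list only.

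Cholangiocyte markers had fewer genes with a siRNA peak than with a control peak. Of 28 genes, 19 had a control peak (percentile 78.4) and 15 a siRNA peak (percentile 14.2). KRT7, a biliary keratin, GGT1, TFF3, SPP1 and PROM1 had a control peak only. The control-only peaks were weak: KRT7, with the highest −log10 q, had 12.9 and a fold enrichment of 2.88. KRT19, SLC4A2, ELF3 and MUC1 had the strongest control peaks and a peak in both lists. For KRT19, ELF3 and MUC1 the strongest peak of each list lay outside the gene, within 1 kb of its boundary, and may belong to a neighbouring gene. For SLC4A2 the strongest peaks of the lists lay at opposite gene ends (151057905 to 151058510 in the control and 151076897 to 151077469 in the siRNA list). Against random lists with as many control peaks, the difference of 4 genes stood at a percentile of 0.825, and at up to 2.93 under the other settings tried. With equal numbers of peaks it stood at 2.81 and immune markers stood lower, at 1.92, so cholangiocyte markers were not set apart under every setting. At the other end, 6 of the 22 lists stood above the 97.5th percentile of the difference: zinc finger genes of chromosome 19 (99.7), histone chaperones (99.6), ribosomal proteins (99.0), silencing factors of transposable elements (98.6), mitotic genes (97.9) and DNA damage response genes (97.8). Of these only the zinc finger genes stayed above it under every setting tried, at 98.1 or more. They had 16 more siRNA genes, against a mean of 2.73 in random lists. Histone chaperones, ribosomal proteins, silencing factors and DNA damage response genes had 2 more each, against −1.30, −3.46, −1.48 and −0.94. Mitotic genes had 1 more, against −1.74. For the lists other than the zinc finger genes, a high percentile is thus not a gain alone, since their matched random genes lost peaks on average. Random genes were not matched on peak strength, which sharing followed, or on chromosome. Chromosome 19 had the highest ratio of siRNA to control peaks among the autosomes (1.35).

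Zinc finger genes on chromosome 19, many of which silence transposable elements, had 179 control and 195 siRNA genes of 250. ZNF875 had a control peak only, and 17 genes a siRNA peak only, among them ZNF491, ZNF418, ZNF878 and ZNF234. ZNF566 (fold enrichment 14.4) and ZNF414 had the strongest control peaks. Zinc finger genes on other chromosomes had 196 and 214 of 268, with 5 in the control list only and 23 in the siRNA list only. Of the other protein-coding genes of chromosome 19, 770 and 837 of 1201 had a peak, with 70 in the control list only and 137 in the siRNA list only. Between the lists, the share of chromosome 19 zinc finger genes went from 71.6% to 78.0%. It went from 73.1% to 79.9% for zinc finger genes elsewhere and from 64.1% to 69.7% for the other chromosome 19 genes. The gain was thus not particular to zinc finger genes of chromosome 19.

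Hepatocyte markers had 4 control and 9 siRNA genes of 28. TAT, HPX, HNF4A and SERPINA1 had a peak in both lists. For HNF4A the strongest lay at opposite gene ends (44355324 to 44355764 in the control and 44433810 to 44434264 in the siRNA list). CPS1, AMBP, ASGR1, FGG and G6PC1 had a peak in the siRNA list only. That gain was near the mean of 4.88 genes in random lists with as many control peaks. Fibroblast markers had 7 and 8 of 20, endothelial markers 6 and 7 of 18, immune markers 9 and 10 of 24, neuronal markers 5 and 8 of 24 and germline genes 6 and 7 of 23. Over the 22 lists, 16 had more genes in the siRNA list and 3 fewer. With equal numbers of peaks per list these counts became 8 and 10, as the direction changed, or reached or left 0, in 10 of the 22 lists.

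A comparison of 8 classes of annotated genes, added after the data had been seen, set tRNA genes apart. tRNA genes, which RNA polymerase III transcribes, were overlapped by a peak at 180 of 443 genes in the control list (40.6%, 36.0 to 45.4). In the siRNA list 102 had a peak (23.02%, 19.2 to 27.2). There were 90 tRNA genes in both lists, 90 in the control list only and 12 in the siRNA list only, and random placement gave 1.47% and 1.91%. Protein-coding genes (74.2% and 77.9%), lncRNA genes (36.9% and 41.2%) and pseudogenes (6.03% and 8.36%) had more genes in the siRNA list. Genes of snRNAs had 52 and 43 of 154, with 10 in the control list only and 1 in the siRNA list only. Genes of rRNAs had 16 and 14 of 49, with 3 in the control list only and 1 in the siRNA list only.

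**Figure D3:**
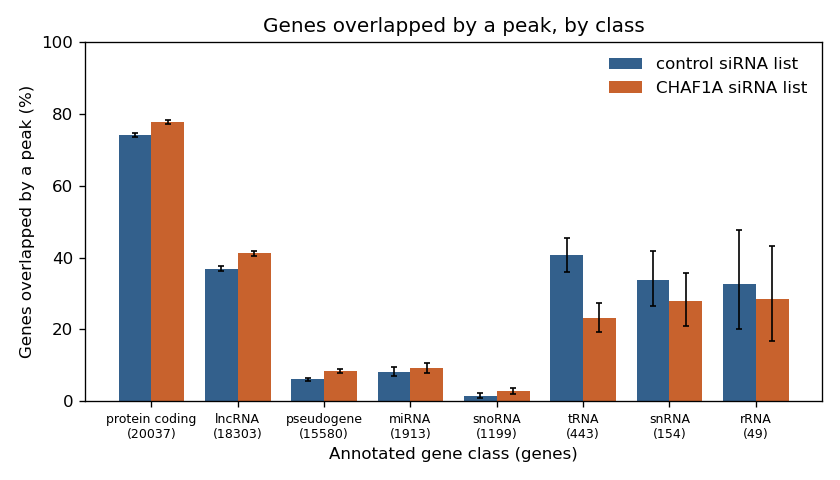
Share of annotated genes overlapped by a peak (percent, vertical axis) for 8 gene classes (horizontal axis, number of genes in brackets), in the control and the siRNA list; bars are shares with 95% exact intervals. tRNA genes stand at 40.6% and 23.02%, while protein-coding genes stand at 74.2% and 77.9%.

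Much of the tRNA difference lay in the cluster on chromosome 6 (26286526 to 28989083), where 50 of 144 tRNA genes had a control peak and 12 a siRNA peak. The core histone genes of an overlapping stretch (26017032 to 27893891) had 27 and 30 of 51. The strongest control peaks without a siRNA peak were those of TRX-CAT1-3 (26312881 to 26313159, fold enrichment 5.64), TRR-TCG2-1 (26322661 to 26323197, 6.66), TRK-CTT2-4 and TRT-AGT2-2. Off chromosome 6 the counts were 128 and 89 of 288 tRNA genes.

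**Figure D4:**
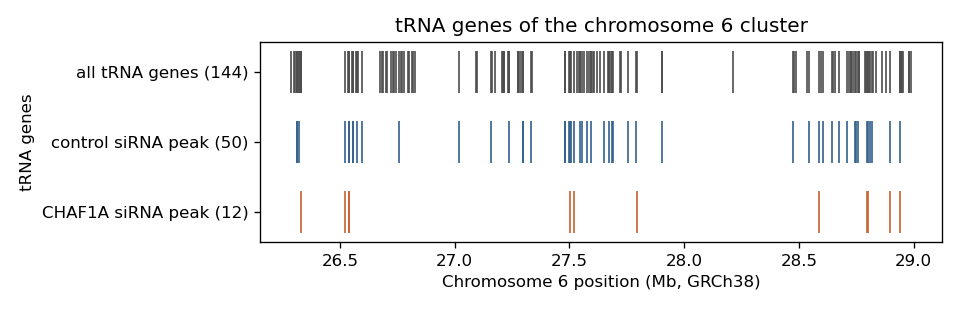
Positions of tRNA genes in the chromosome 6 cluster (Mb, horizontal axis), for all 144 genes, the 50 with a control peak and the 12 with a siRNA peak; each line is a gene. Control peaks are spread over the cluster and siRNA peaks are at fewer genes.

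Chromosome X had the highest ratio of siRNA to control peaks among the autosomes and X, a comparison also added after the data had been seen. It held 1869 control and 3077 siRNA peaks, a ratio of 1.65, against 1.12 to 1.35 for the 22 autosomes, with chromosome 19 the highest of them. Within X the ratio was 2.14 both from 20 to 40 Mb and from 60 to 80 Mb, 1.06 from 100 to 120 Mb and 0.800 from 80 to 100 Mb, where there were 20 control peaks. After the siRNA list was thinned to the depth of the control list, X was at 1.46 and the autosomes at 1.02 to 1.25.

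**Figure D5:**
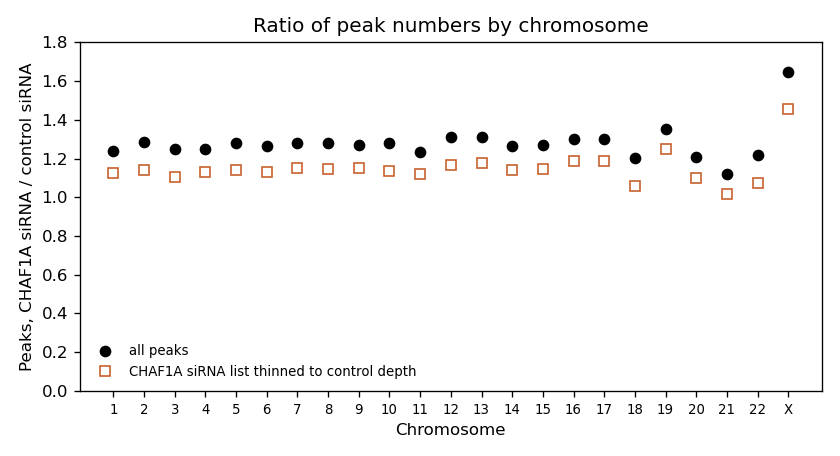
Ratio of siRNA to control peak numbers (vertical axis) for chromosomes 1 to 22 and X (horizontal axis); dots are all peaks and open squares the siRNA list thinned to the control depth. X stands at 1.65 and 1.46, above chromosome 19 at 1.35 and 1.25.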

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

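The tests of depth by thinning, and all alternatives for tRNA genes and chromosome X, were chosen after the results had been seen. No paired analysis was possible because each group has 1 peak list, in which its 2 samples cannot be told apart; for the same reason no sample could be left out. The alternatives on transcript 5′ ends, on repeats and on GC content were not run, since strand and sequence were not used here. With −log10 q of at least 10, 37115 control and 38805 siRNA peaks were left, 68.4% and 64.7% of them were shared, 26.1% and 25.8% lay at gene ends, and 930 genes had a control peak only and 1042 a siRNA peak only, as fewer weak peaks entered. With −log10 q of at least 5, sharing was 64.0% and 50.2%, the share at gene ends 18.9% and 16.6%, and 5 gene lists had fewer genes in the siRNA list. With equal numbers of peaks, sharing was 57.5% of control and 56.2% of siRNA peaks, 17.5% of siRNA peaks lay at gene ends, 1227 genes had a control and 1252 a siRNA peak only, and 8 gene lists had more and 10 fewer siRNA genes. With the siRNA list thinned to the control depth, 87831 peaks were left, sharing was 59.8% and 51.0%, 16.1% of siRNA peaks lay at gene ends, 1088 genes had a control and 1457 a siRNA peak only, and 9 gene lists had more siRNA genes. A 50% reciprocal overlap gave sharing of 44.0% and 34.4%. The 3 kb window put 24.9% and 22.8% of peaks at gene ends, with 5 gene lists having fewer siRNA genes. Above the 97.5th percentile were 12 control and 11 siRNA lists, 10 and 10 with the 3 kb window, and 11 and 10 without matching on gene length. Thus the larger control share of shared peaks held under each setting run, and the gap narrowed most with equal numbers. As the main setting had similar numbers shared (47221 control and 46416 siRNA peaks), the shorter list had the larger share. With equal numbers the order held by little (57.5% and 56.2%). The gap in the main setting therefore largely reflects list length, and the order is not read as a result about control peaks. tRNA genes had fewer siRNA than control peaks under every setting run; with a 200 bp margin the shares were 48.3% and 31.2%, and without chromosome 6 the siRNA share was 30.9%. The ratio of X peaks relative to autosomes stayed between 1.22 and 1.30. The sign of the difference between lists changed, or reached or left 0, in 32 of 88 combinations of gene list and setting, and 9 of the 22 lists kept a direction under every setting run. Of these, more siRNA genes were found for chromosome 19 zinc finger genes, histone chaperones, silencing factors of transposable elements, DNA damage response genes, hepatocyte and neuronal markers, and fewer for cholangiocyte markers, replication fork genes and immediate early genes. Depth limits which weak peaks are called, and without replicate lists the spread between samples is unknown.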

Other observations

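At sites shared by both lists, the recovered signal was a little lower after the CHAF1A siRNA. At 22646 shared summits no more than 50 bp apart, the median log2 ratio of siRNA to control pileup, each relative to its genome background, was −0.25 (−0.25 to −0.24), and 74.97% of summits were lower. At the 11330 stronger summits, ranked on both lists together, it was −0.29, at gene ends −0.26 and on chromosome X −0.13. At 42 summits on tRNA genes it was −0.62 (−0.90 to −0.46). Ratios of this kind do not separate a change in binding from a change in the share of background reads, and they leave out sites called in 1 list only.

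The tests below of tRNA genes, of depth for chromosome X and of peak width were chosen after the results had been seen; the others were fixed before, though afterwards the rule for chromosome X DNA was made stricter and the median fall was taken from summits ranked on both lists in place of the control list. tRNA genes had fewer siRNA than control peaks, a pattern picked out from 8 gene classes. If the CUT&Tag data set the background, its ratio of 1.34, siRNA over control, argues against a shallower siRNA library. A general loss of peaks of that strength and width would have kept 86.6% ± 2.75 (binomial SE) of the 153 control peaks on tRNA genes, and 63.4% were kept. Reads shared between identical copies would leave single-copy tRNA genes as they were, yet their share went from 38.6% (lower bound 31.9) to 18.8% of 202. Single-copy genes were those whose sequence number, read from the gene symbol, was held by 1 gene. Reads shared between similar but not identical copies were not tested. A loss of CHAF1A signal at tRNA genes through its knockdown, a difference between single samples and a difference in how open these genes were to the transposase stay open, and none of them was tested.

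Chromosome X had more siRNA peaks than its share, a pattern picked out from 24 chromosomes. On the same condition about the background, the ratio for X was 1.46 after thinning, above the highest autosome at 1.25. That does not decide on greater depth. The thinned siRNA list still held 87831 peaks against 76313 control peaks, and thinning was not checked for weak peaks near the threshold. A gain of X DNA in the siRNA cells remains open as well. The local background at 426 shared summits had a median log2 ratio of 0.13 on X and 0.11 on chromosome 19, the highest autosome, and the difference of 0.02 (−0.00 to 0.05) included 0. Whether that background came from the same libraries as the peaks is not known, so a different copy number and a different CHAF1A signal could not be separated here.

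Of 18865 control peaks with −log10 q of at least 20, 1713 (9.08%) had no siRNA peak, and of 15272 such siRNA peaks, 484 (3.17%) had no control peak; since −log10 q depends on depth, these shares are not compared. Draws for counting noise at the calling threshold lost 0 of them, and draws for the same fall of enrichment at every peak, by the median of the stronger shared summits, 0.04 ± 0.196 (SD). Neither number decides, although a bound had been fixed beforehand: peaks chosen so far past the threshold can hardly be lost in such draws, the draws hold no spread between samples, and the median comes from sites that stayed shared. Stacks of single fragments, taken as peaks under 249 bp wide, made up 32.4% of them (upper bound 34.7) and 5.55% of the shared ones. Most were thus wider than this cut. Fragment length was not known, and stacks of longer fragments would be wider too, so the share of stacks is not limited by this value. With 1 list per group, the knockdown and differences between samples cannot be told apart as sources of the unshared peaks. Of these 1713 peaks, 8.99% lay at gene ends, against 36.4% of the shared ones, and of the 484 siRNA peaks 11.2%, against 39.8%. Shared and unshared peaks were not matched on strength for these shares.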
